A study of Mus musculus with 8 samples.

How the data were processed

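The series profiled total RNA of mouse mesenchymal stromal cells, isolated from the inguinal fat of male FVB mice aged 12 months, on biotin-labelled Affymetrix mouse arrays. The cells carried the lentiviral plasmid backbone pLKO.1 in 1 of 3 forms: empty, with a scrambled hairpin, or with a hairpin against Irf7. There were 2 empty vector arrays, 2 scramble arrays and 4 shIRF7 arrays, and the group and replicate number of each came from its label. Nothing in the labels says whether replicates came from separate cultures, animals or infections. The p-value of a gene therefore measures the spread between these arrays, which may be technical. The number of arrays limits the precision.

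The deposited table holds 1 log2 value per probe set and array, which the authors made with RMA (background correction, normalization between arrays and summary of probes) in Affymetrix Expression Console 1.4.1.46, per the submitters' processing notes. The log2 scale was read from the deposited values, which ran from 1.66 to 18.9. The genome build behind the probe sets is not given in the sources used here, so no coordinates are reported. No array column was left unused (0 columns). Of 28846 probe sets, 19572 had 1 gene symbol in the platform annotation, 0 had several and 9274 had none. All 19572 gene identifiers matched a RefSeq gene table of assembly GRCm38.p6, which was used only for current symbols. For the 55 genes with several probe sets the probe set with the highest mean over the 8 arrays was kept, which left 19505 genes. The table also holds 5222 negative and 1324 positive control probe sets, used here only to describe the arrays.

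The deposited log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with a mean per group over all 8 arrays, so that the 3 groups shared a spread per gene (5 residual degrees of freedom and 2.68 prior degrees of freedom). The comparisons were shIRF7 against the equally weighted mean of both controls, shIRF7 against scramble, shIRF7 against empty vector, and scramble against empty vector, each adjusted by Benjamini-Hochberg over all genes with a threshold of 0.05. An SE is the moderated standard error of limma, and adjusted p-values in the text are from these fits unless another test is named. Irf7 and the mean of each gene list were also compared between the 4 shIRF7 and 4 control arrays with a two-sided exact permutation test, in which 70 assignments make 0.0286 the smallest possible p.

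Gene lists, 28 in all and of 652 distinct genes, were written from general knowledge of interferon responses, stromal cells and their differentiation, growth, stress and metabolism, with markers of other cell types that a fat pad could hold. Of their genes 597 matched by symbol, 2 through an older symbol, and 53 did not match. Each list was tested with camera of limma with a preset correlation of 0.01 and Benjamini-Hochberg over the 28 lists. This test compares the genes of a list with other genes, so its p-values do not measure how far the list varies between arrays. Camera was then run with a correlation estimated per list. That version also takes the 5 residual degrees of freedom, where the preset version takes about as many as there are genes. A call lost there can reflect either change. The last test was fry, which does not compare a list with other genes. The genes named were Irf7; among genes past the threshold in shIRF7 against both controls whose 4 shIRF7 values all lay on the same side of all 4 control values, the 10 largest rises and 10 largest falls; the 3 largest rises and falls past the threshold in each other comparison; and per list up to 4 members past the threshold, or otherwise up to 2 members with the largest change. Predicted genes, Riken clones, small RNAs, olfactory and vomeronasal receptors and receptor segments were left out of these rankings. Genes, groups, comparisons, lists, this rule and the alternatives were fixed before the data were examined, apart from those said to have been added later.

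The fit was tested on simulated data of the same size, 10 runs of 200 changed genes among 19505, for shIRF7 against both controls. It recovered 42.2% of genes changed by 1 on the log2 scale, 85.2% by 2, 98% by 3 and 99% by 4, and 5.44% of its calls were false. In 10 separate runs only the interferon-stimulated list was lowered, by 1 on the log2 scale. There camera called the lowered list in 100% of runs and 0.741% of untouched lists. The simulated genes varied independently, with no structure among the arrays, while the correlation estimated within the real lists reached 0.962. The simulated rates for genes and for lists therefore do not carry over. Other splits of the real arrays gave a median of 8 of 28 lists, and Irf7, at -3.79, missed the threshold in the real data.

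The alternatives tried were a filter on dim genes, eBayes with trend and robust fitting, cyclic loess between arrays, the mean of a gene's probe sets, all probe sets, both controls as 1 group, the replicate number as a block, array weights, a fold of at least 1.5, an adjusted p under 0.01, other list tests, and leaving out each array in turn. Added after the data were seen were the S phase list mean as a covariate, shIRF7 replicates 2 and 3 averaged, list tests on the 3 other comparisons, and the permutation test of list means.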

Results

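Gene expression was measured in mesenchymal stromal cells of mouse inguinal fat that carried an empty lentiviral vector (2 arrays), a scrambled hairpin (2 arrays) or a hairpin against Irf7 (shIRF7, 4 arrays). Irf7 encodes a transcription factor that drives type I interferon and interferon-response genes, and the series concerns its part in the ageing of these cells. Median log2 values of the named probe sets lay between 5.36 and 5.46 on the 8 arrays, and 31.6% to 36.8% of named probe sets exceeded the 95th percentile of the negative controls. Medians of the negative controls followed the replicate number across groups: they were 4.21, 4.26 and 4.18 in replicate 1 of empty vector, scramble and shIRF7, and 4.55, 4.56 and 4.56 in replicate 2. Replicates 3 and 4 exist only for shIRF7, with negative control medians of 4.54 and 4.33. Differences within replicates 1 and 2 are therefore given beside the pooled ones for Irf7, the genes that passed and the gene lists of shIRF7 against both controls.

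Irf7, the targeted gene, was lower in all 4 shIRF7 arrays than in all 4 controls. It measured 9.55 and 9.61 in the empty vector arrays, 9.56 and 9.76 in the scramble arrays, and 4.42, 5.66, 6.47 and 6.79 in shIRF7 replicates 1 to 4. The means were 9.62 ± 0.096 (SD, n = 4) in the controls and 5.83 ± 1.06 (SD, n = 4) in shIRF7, a log2 difference of -3.79 (SE 0.48, 95% interval -4.91 to -2.66) or 13.8-fold. The exact permutation test gave p = 0.0286, the smallest that 4 against 4 arrays allow. In limma across all genes Irf7 missed the threshold (adjusted p = 0.069), with 14 genes of smaller p. The difference was -5.14 within replicate 1 and -4.02 within replicate 2. The adjusted p fell to 0.0254 without shIRF7 replicate 1 (difference -3.31), and shIRF7 replicate 1 lay near the negative controls, where a fold change understates the difference.

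In shIRF7 against both controls 6 genes fell and 0 rose among 19505. Ifi27l2a, an interferon-stimulated gene, fell most, from 8.47 ± 0.76 to 4.46 ± 0.44 (SD, n = 4 each), a log2 difference of -4.01 (SE 0.37, 16.1-fold, adjusted p = 0.0483). Bst2, which encodes tetherin and holds budding virions at the cell surface, fell by 2.89 on the log2 scale (SE 0.30, 7.42-fold). Adar, an adenosine deaminase of double-stranded RNA, fell by 1.63 (SE 0.17, 3.10-fold). The other 3 genes belong to none of the lists. Cdsn, a corneodesmosome adhesion protein, fell by 3.26 (SE 0.33, 9.56-fold). Hs2st1, a heparan sulfate sulfotransferase, fell by 2.18 (SE 0.22, 4.54-fold). Rnf141, a RING finger protein, fell by 1.96 (SE 0.13, 3.88-fold, adjusted p = 0.0136). The adjusted p was 0.0483 for Cdsn, Bst2, Hs2st1 and Adar. All 6 genes were lower in 4 of 4 shIRF7 arrays than in every control. Within replicates 1 and 2 the differences of Ifi27l2a were -3.97 and -4.57, of Cdsn -3.47 and -3.10, and of Bst2 -2.99 and -3.26. Those of Hs2st1 were -1.90 and -1.80, of Rnf141 -1.80 and -1.89, and of Adar -1.90 and -1.66. In shIRF7 Ifi27l2a lay close to the mean negative control median of 4.40, so its fold is understated. Without adjustment 1583 genes had a limma p under 0.05 (783 higher and 800 lower), where chance gives 5% of all genes, while 27 genes had an adjusted p under 0.1. In 547 genes all 4 shIRF7 values lay below all 4 control values and in 503 above. Chance gives 1.43% or 279 genes each way if the 8 arrays are independent. That is not known, and shIRF7 replicates 2 and 3 were the closest pair (SD of their difference over genes 0.322). The excess over 279 may therefore be smaller than it seems. Chance counts given for the lists below rest on the same assumption. Limits: the count was 28 without shIRF7 replicate 1 (20 lower and 8 higher), 2 without empty vector replicate 2, 3 without shIRF7 replicate 4, and 0 without scramble replicate 1, scramble replicate 2, shIRF7 replicate 2 or shIRF7 replicate 3. It was also 28 with both controls as 1 group of 4 (25 lower and 3 higher), and 0 with shIRF7 replicates 2 and 3 averaged. With the replicate number as a block only replicates 1 and 2 inform the difference, and 2 residual degrees of freedom remained. That fit called 0 genes in limma (691 at an unadjusted p under 0.05), with Irf7 at -4.58 (adjusted p = 0.267). Of the 8 fits that each left out 1 array, Rnf141 passed in 4 (without empty vector replicate 1 or 2, or shIRF7 replicate 1 or 4) and Ifi27l2a in 2 (without empty vector replicate 1 or shIRF7 replicate 1). Cdsn, Hs2st1 and Adar passed in 1 (without shIRF7 replicate 1) and Bst2 in 1 (without shIRF7 replicate 4). The highest adjusted p was 0.303 for Ifi27l2a, 0.28 for Hs2st1, 0.156 for Rnf141 and 0.316 for the other 3.

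**Figure D1:**
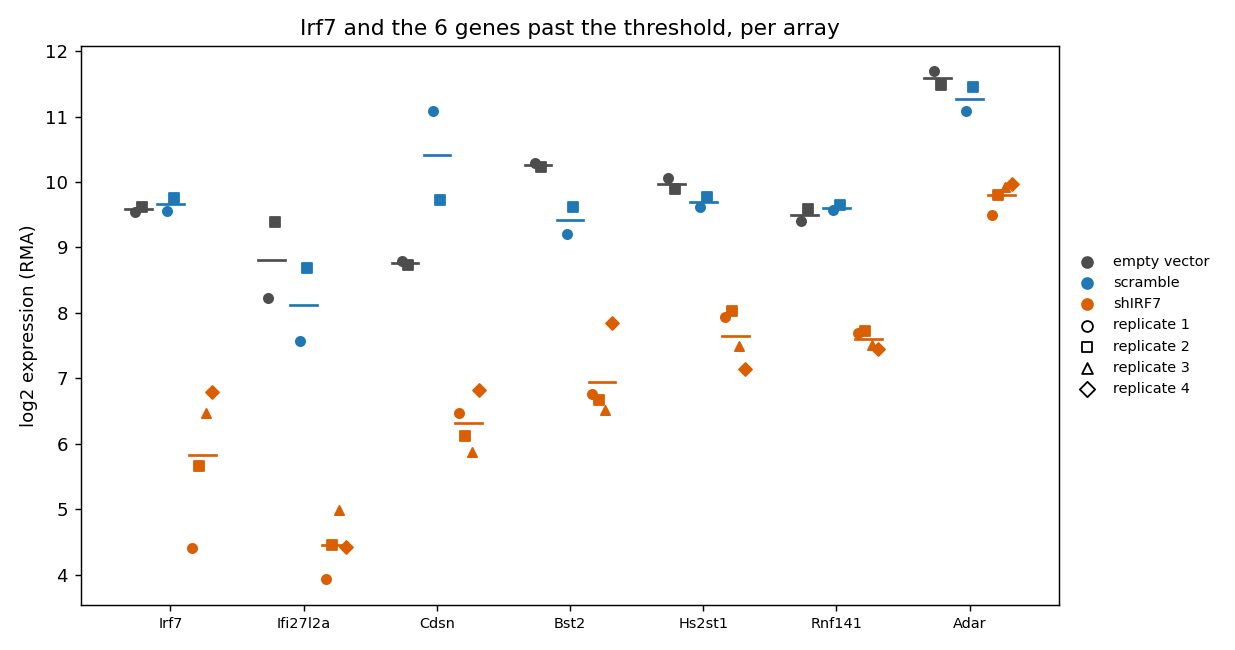
Log2 expression (RMA) of Irf7 and of the 6 genes that fell in shIRF7 against both controls, with 1 point per array, colour for the group, shape for the replicate number and a bar for the group mean. The shIRF7 values of Irf7 ran from 4.42 to 6.79 and all control values from 9.55 to 9.76.

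Interferon-response genes were lower in shIRF7 as a group. Among interferon-stimulated genes, the effectors made in response to interferon, the median log2 difference over 46 measured members was -1.21 (mean -1.48). Over all genes 3 fell, 31 fell when adjusted over the list alone, and 0 rose. In 28 members all 4 shIRF7 values lay below all control values where chance gives 0.657. The list mean of the shIRF7 arrays lay -2.07, -1.45, -1.46 and -0.96 from the control mean, against 0.03, 0.19, -0.27 and 0.05 in the controls. The list median was -1.54 within replicate 1 and -1.16 within replicate 2. The list fell with camera (adjusted p = 1.2e-32). That camera call was lost with an estimated correlation and the 5 residual degrees of freedom that come with it (adjusted p = 0.17). With fry the adjusted p was 0.0289. Interferon-inducible GTPases, which act against intracellular pathogens, had a median of -1.37 over 12 members. Over all genes 0 fell, 9 fell when adjusted over the list alone, and 8 lay below all controls where chance gives 0.171. Gvin1 measured 10.2 ± 0.036 in the controls and 5.74 ± 1.67 in shIRF7 (SD, n = 4 each, log2 difference -4.50, adjusted p = 0.148, and 0.0494 without shIRF7 replicate 1), and Gbp3 differed by -2.90 (adjusted p = 0.174). Within replicates 1 and 2 Gvin1 differed by -2.66 and -5.36, and Gbp3 by -4.06 and -2.98. Gvin1 in shIRF7 replicates 2 and 3 (4.88 and 3.90) lay near or below the mean negative control median of 4.40. Its pooled difference and that within replicate 2 are therefore understated, but not that within replicate 1 (7.59 in shIRF7). This list fell with camera (adjusted p = 4.79e-12; adjusted p = 0.17 with an estimated correlation) and had adjusted p = 0.0354 with fry, and its median was -2.66 within replicate 1 and -1.16 within replicate 2. Oas1a and Oas1g, Ifit3 and Ifit3b, and members of the Gvin, Tgtp and H2 families have near-identical copies whose probes may not separate them, so their values are uncertain.

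Genes of MHC class I antigen presentation had a median difference of -0.30 over 20 members, with 4 fallen when adjusted over the list alone. Psmb8, an immunoproteasome subunit, differed by -1.69 (adjusted p = 0.488) and Tap1, a peptide transporter, by -1.64 (adjusted p = 0.174). The difference of Psmb8 was -3.68 within replicate 1 and -0.31 within replicate 2, that of Tap1 -2.23 and -1.96. Psmb8 in shIRF7 replicate 1 (4.25) lay below the mean negative control median of 4.40. The list fell with camera (adjusted p = 5.66e-05; adjusted p = 0.687 with an estimated correlation), and its median was -0.98 within replicate 1 and -0.27 within replicate 2. The list mean lay -0.98 from the control mean in shIRF7 replicate 1 and -0.25, -0.25 and -0.24 in the others. Without shIRF7 replicate 1 the median was -0.18 (adjusted p = 0.0156). Genes of interferon signalling and of RNA or DNA sensing had a median of -0.15 over 28 members, 6 of which fell when adjusted over the list alone. Ifih1, the RNA sensor MDA5, differed by -2.11 (adjusted p = 0.0737) and Dhx58, a related sensor, by -1.92 (adjusted p = 0.174). Within replicates 1 and 2 Ifih1 differed by -2.31 and -2.57, and Dhx58 by -2.20 and -2.23. That list fell with camera (adjusted p = 0.0322; adjusted p = 0.745 with an estimated correlation), with medians of -0.51 within replicate 1 and -0.05 within replicate 2. Its call ended, with a median just above 0, without empty vector replicate 1 (0.018, adjusted p = 0.286), scramble replicate 2 (0.011, adjusted p = 0.0661) or shIRF7 replicate 1 (0.019, adjusted p = 0.419). The call held at a smaller median without empty vector replicate 2 (-0.094) or scramble replicate 1 (-0.070).

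**Figure D2:**
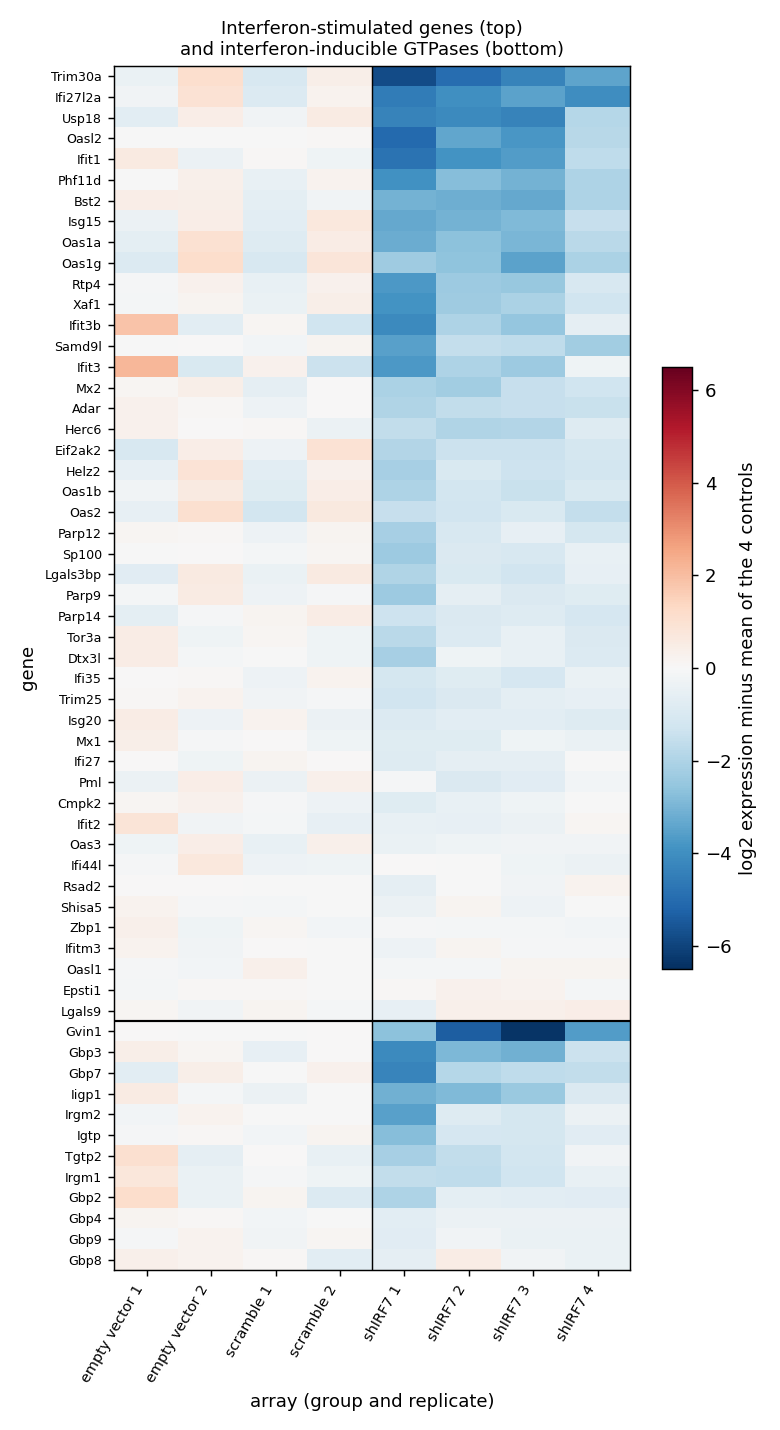
Log2 expression of 46 interferon-stimulated genes (top) and 12 interferon-inducible GTPases (bottom) in each of the 8 arrays, minus the mean of the 4 controls; blue is lower and red is higher, and genes are ordered by the log2 difference. In 28 of the 46 and 8 of the 12 all 4 shIRF7 values lay below all control values.

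Outside the interferon response, oxidative phosphorylation genes, which encode subunits of the mitochondrial respiratory chain, were higher in shIRF7 by a median of 0.25 over 28 members. In 8 members all 4 shIRF7 values lay above all controls, where chance gives 0.4, 0 rose over all genes or when adjusted over the list alone, and the list medians within replicates 1 and 2 were 0.19 and 0.18. Sdhc differed by 0.68 (adjusted p = 0.44) and Ndufb5 by 0.59 (adjusted p = 0.61). Within replicates 1 and 2 Sdhc differed by 0.11 and 1.12, and Ndufb5 by -0.24 and 1.02. The list rose with camera (adjusted p = 1.55e-05; adjusted p = 0.17 with an estimated correlation) and had adjusted p = 0.0289 with fry. Cholesterol synthesis genes rose with camera by a median of 0.57 over 18 members (adjusted p = 8.51e-05; adjusted p = 0.745 with an estimated correlation), 1.09 within replicate 1 and 0.49 within replicate 2. Pmvk, a kinase of that pathway, differed by 1.21 (adjusted p = 0.477), with 1.24 within replicate 1 and 1.65 within replicate 2. The cholesterol call ended without empty vector replicate 1 (median 0.16, adjusted p = 0.33). Its median was 0.98 without empty vector replicate 2 and 0.87 without shIRF7 replicate 4.

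The other lists that passed camera lost the call without single arrays. Genes of mitosis and proliferation rose by a median of 0.48 over 28 members (adjusted p = 0.0366; adjusted p = 0.823 with an estimated correlation), yet the median was 2.38 within replicate 1 and -1.28 within replicate 2. Without empty vector replicate 1 the list fell instead (-0.49, adjusted p = 0.00133). Its call ended without scramble replicate 1 (0.07, adjusted p = 0.946), shIRF7 replicate 1 (0.35, adjusted p = 0.284) or shIRF7 replicate 4 (0.44, adjusted p = 0.11), and the median was 1.60 without empty vector replicate 2 and 1.02 without scramble replicate 2. Genes of the unfolded protein and integrated stress response fell by a median of 0.29 over 22 members (adjusted p = 0.0095; adjusted p = 0.745 with an estimated correlation), with 0.33 within replicate 1 and -0.88 within replicate 2. This call ended without empty vector replicate 2 (0.011, adjusted p = 0.718) or scramble replicate 2 (-0.26, adjusted p = 0.153), and the median was -0.62 without empty vector replicate 1. Glycolysis and hypoxia genes had a median of -0.17 over 23 members (adjusted p = 0.0183; adjusted p = 0.745 with an estimated correlation), 0.14 within replicate 1 and -0.47 within replicate 2. They lost the call without empty vector replicate 2 (-0.053, adjusted p = 0.718), scramble replicate 2 (-0.068, adjusted p = 0.224) or shIRF7 replicate 4 (-0.071, adjusted p = 0.141). The glycolysis median was -0.46 without empty vector replicate 1 and -0.31 without scramble replicate 1. Contractile and TGF-beta-induced genes had a median of -0.40 over 22 members (adjusted p = 0.0369; adjusted p = 0.823 with an estimated correlation), 0.72 within replicate 1 and -1.25 within replicate 2. Ccn2 measured 16.1 in shIRF7 replicate 1 and 9.69 in replicate 2. The contractile call ended without empty vector replicate 1 (-0.32, adjusted p = 0.353), scramble replicate 1 (-0.28, adjusted p = 0.254), shIRF7 replicate 2 (-0.14, adjusted p = 0.53) or shIRF7 replicate 3 (-0.12, adjusted p = 0.602). The contractile median was -0.999 without shIRF7 replicate 1 and -0.63 without shIRF7 replicate 4. With the replicate number as a block both the contractile call (-0.16, adjusted p = 0.719) and the glycolysis call (-0.096, adjusted p = 0.102) ended. Collagens and other matrix genes had a median of -0.24 over 27 members (adjusted p = 0.0322; adjusted p = 0.745 with an estimated correlation), -0.45 within replicate 1 and -0.11 within replicate 2. The collagen list lost the call without empty vector replicate 1 (-0.062, adjusted p = 0.724), scramble replicate 1 (-0.19, adjusted p = 0.142) or shIRF7 replicate 1 (-0.29, adjusted p = 0.176), and its median was -0.46 without empty vector replicate 2. Chemokines and inflammatory cytokines had a median of -0.085 over 35 members (adjusted p = 0.0322; adjusted p = 0.23 with an estimated correlation; fry adjusted p = 0.0354), -0.17 within replicate 1 and -0.03 within replicate 2. The chemokine call ended without empty vector replicate 1 (-0.12, adjusted p = 0.0941), empty vector replicate 2 (-0.13, adjusted p = 0.0745), scramble replicate 1 (-0.084, adjusted p = 0.0552), scramble replicate 2 (-0.11, adjusted p = 0.0661) or shIRF7 replicate 1 (-0.049, adjusted p = 0.17). The chemokine median was -0.16 without shIRF7 replicate 2 and -0.14 without shIRF7 replicate 3. In the collagen and chemokine lists 1 member each fell when adjusted over the list alone. Ccl5 differed by -1.36 (adjusted p = 0.21), with -1.40 within replicate 1 and -1.67 within replicate 2; its shIRF7 values (4.17 to 5.08) lay near the mean negative control median of 4.40, so the size of the difference is uncertain. Ccl2 differed by -1.55 (adjusted p = 0.533), but by 0.45 within replicate 1 and -2.34 within replicate 2. In all, camera called 12 lists, 9 lower and 3 higher, against 0 with an estimated correlation and 4 with fry (3 lower and 1 higher). The exact permutation test of list means gave 6 lists p = 0.0286, the smallest it allows. They were the interferon-stimulated, GTPase, MHC class I, interferon signalling, chemokine and oxidative phosphorylation lists. At least 17 of the 28 lists at that p would be needed for any to pass after adjustment, so fewer lists than that could not pass it.

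**Figure D3:**
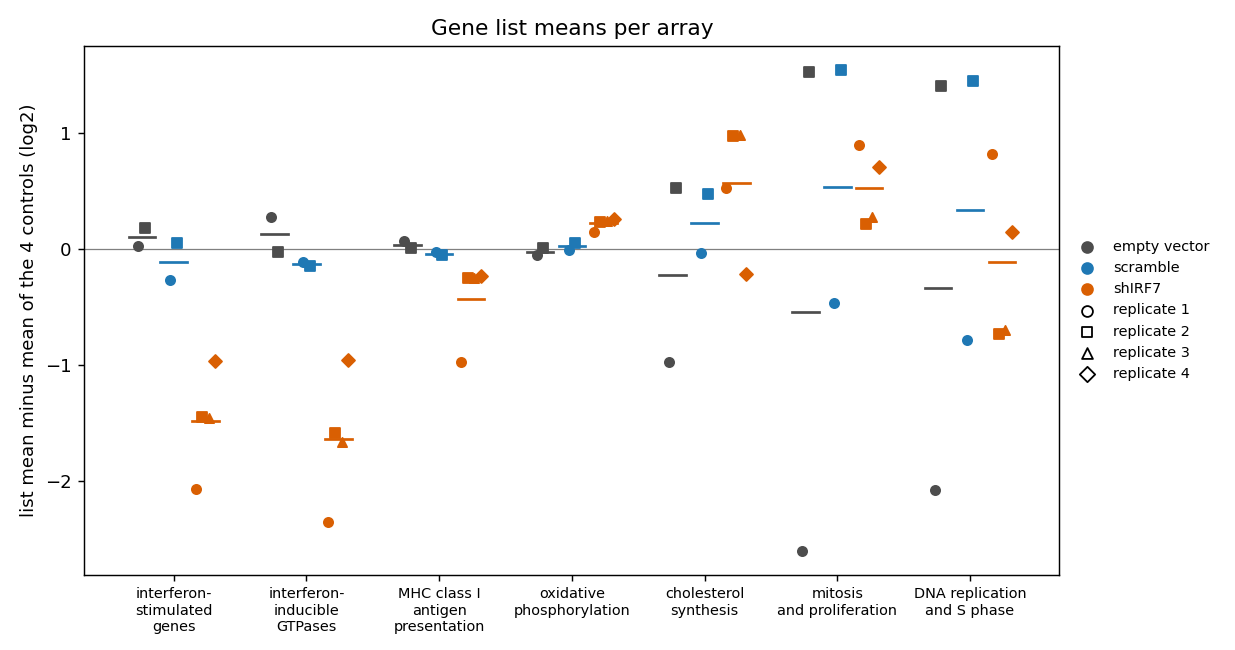
Mean of each gene list per array, minus the mean of the 4 controls (log2), with colour for the group, shape for the replicate number and a bar for the group mean. The interferon-stimulated list lay at -2.07, -1.45, -1.46 and -0.96 in shIRF7 replicates 1 to 4, while the mitosis list lay at -2.61 in empty vector replicate 1 and 1.53 in replicate 2.

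The remaining lists did not pass camera, and 0 of their members passed the limma threshold over all genes or adjusted over the list alone. Genes of senescence and cell-cycle arrest had a median difference of -0.09 over 22 members (adjusted p = 0.58), p53 targets 0.07 over 22 (adjusted p = 0.479), and S phase genes -0.08 over 28 (adjusted p = 0.739). The S phase median was 2.36 within replicate 1 and -2.11 within replicate 2. The list rose without empty vector replicate 2 (0.76, adjusted p = 0.000165) and fell without empty vector replicate 1 (-1.04, adjusted p = 1.81e-06) or scramble replicate 1 (-0.61, adjusted p = 0.00645). Cdkn2a, the cell-cycle inhibitor locus that marks senescence, measured 5.17 ± 1.26 in the controls and 3.89 ± 1.01 in shIRF7 (SD, n = 4 each, adjusted p = 0.707), and differed by -2.48 within replicate 1 and -0.90 within replicate 2. Its shIRF7 replicates 1 to 3 (3.60, 3.37 and 3.20) and scramble replicate 2 (4.10) lay below the mean negative control median of 4.40, so the size of these differences is uncertain. Its pooled difference of -1.28 was -0.66 without empty vector replicate 1 (6.93) and -1.91 without empty vector replicate 2. The adipocyte list had a median of 0.03 over 28 members (adjusted p = 0.791), the preadipocyte and Wnt list -0.08 over 18 (adjusted p = 0.479), the osteogenic list 0.14 over 21 (adjusted p = 0.346), and the chondrogenic and tendon list 0.01 over 18 (adjusted p = 0.791). Dlx5, an osteogenic transcription factor, measured 8.60 ± 0.70 in the controls and 10.1 ± 0.57 in shIRF7 (SD, n = 4 each), with all 4 shIRF7 values above the controls (adjusted p = 0.285; 1.45 within replicate 1 and 0.96 within replicate 2). Fabp4, a fatty acid carrier of adipocytes, differed by -0.99 (adjusted p = 0.629), by 0.57 within replicate 1 and -1.68 within replicate 2, and by -1.46 without shIRF7 replicate 1 (adjusted p = 0.0494). Markers of mesenchymal stromal cells had a median of -0.08 over 16 (adjusted p = 0.479), the Nrf2 list 0.07 over 20 (adjusted p = 0.958) and the NF-kappa-B list -0.03 over 16 (adjusted p = 0.799). Of the markers of other cell types, macrophages and leukocytes had a median of -0.06 over 19 members (adjusted p = 0.45), lymphocytes -0.055 over 12 (adjusted p = 0.755) and endothelial cells 0.10 over 15 (adjusted p = 0.479). The median was -0.09 over 11 for pericytes and smooth muscle (adjusted p = 0.479), 0.04 over 14 for epithelial and mesothelial cells (adjusted p = 0.755) and 0.11 over 11 for mature or brown adipocytes (adjusted p = 0.706). Few of those markers exceeded the mean negative control median: 3, 2, 5, 2, 1 and 2 in that order. The list mean differed in sign from its median for the Nrf2 list (-0.02), the NF-kappa-B list (0.01), the chondrogenic list (-0.11) and the epithelial list (-0.07); camera took the sign of the mean for the NF-kappa-B and chondrogenic lists. Within replicates 1 and 2 the medians were 0.056 and -0.10 for senescence, 0.47 and -0.37 for p53 targets, -0.079 and 0.29 for adipocyte genes, and -0.41 and 0.15 for preadipocyte genes. They were 0.23 and -0.047 for osteogenic genes, -0.25 and 0.20 for chondrogenic genes, -0.038 and 0.081 for stromal markers, -0.069 and -0.29 for Nrf2 targets, and -0.11 and 0.18 for NF-kappa-B. For the markers of other cell types, in the order above, they were -0.029 and 0.0077, -0.17 and 0.050, 0.16 and 0.00098, -0.029 and 0.041, 0.011 and 0.091, and -0.058 and 0.077.

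The rule that named 2 members of each list without a passing gene gave 54 genes with adjusted p-values of 0.0737 to 0.945. Those not given above differed without passing. Where a range is given, it is that over fits that each left out 1 array. Among senescence genes Mmp3 differed by -2.14 (range -3.69 to -0.59). Among p53 targets Trp53inp1 differed by 1.67 (range 0.86 to 2.48) and Sesn1 by 1.23. In the NF-kappa-B list Vcam1 differed by 0.67 and Nfkb2 by -0.45 (range -0.60 to -0.18). Among growth genes Ccnb2 differed by 1.42 (range 0.57 to 2.26), Hmmr by 1.13, E2f1 by -0.87 (range -1.36 to -0.37) and Cdc6 by -0.61. Of the differentiation lists, Ebf2 differed by 0.73 and Ccn5 by -1.20. Smpd3 differed by -0.93 (range -1.47 to -0.39), Fmod by -1.33 (range -2.01 to -0.66) and Prg4 by -1.12 (range -1.99 to -0.26). Of the stromal markers, Thy1 differed by -2.15 (-2.16 within replicate 1 and -2.72 within replicate 2) and Mcam by 2.02 (5.97 and 0.24). Mcam differed by 0.62 without shIRF7 replicate 1 (10.7), and its control mean of 4.47 lay near the mean negative control median of 4.40. Of the matrix and contractile genes, Dcn differed by 1.22 (-5.35 within replicate 1 and 4.74 within replicate 2) and Lum by 1.07 (range 0.51 to 1.64). Ccn1 differed by -1.92 (range -2.80 to -1.28) and Ccn2 by -1.39 (range -2.73 to -0.53). Of the stress and metabolic genes, Chac1 differed by -1.46, Trib3 by -0.91 and Adm by -1.85. Gsr and Slc7a11 differed by -1.08 each (ranges -1.47 to -0.68 and -1.53 to -0.62). Dhcr7 differed by 1.12 (range 0.58 to 1.65) and Ndrg1 by -1.52 (range -2.53 to -0.51). Within replicates 1 and 2 Ndrg1 differed by -5.12 and 1.73. Of the markers of other cell types, Cd53 differed by -0.49 (range -1.04 to -0.14) and Elovl6 by 0.68 (range 0.12 to 1.24). In 12 of the 54 a group mean lay below the mean negative control median of 4.40, so the size of their differences is uncertain: Cdkn2a, Axin2, Aif1, Il7r, Ms4a1, Ptprb, Emcn, Myh11, Abcc9, Krt19, Krt8 and Acvr1c. Krt19 differed by -1.75 (adjusted p = 0.383), with -0.18 within replicate 1 and -3.04 within replicate 2. The control means of Krt19 (6.08), Cdkn2a (5.17) and Axin2 (5.03) lay above that median, so these falls may be understated. The sign differed between replicates 1 and 2 in 19 of the 54, also where the range given above has a single sign. They were Ccl2, Vcam1, Nfkb2, Trp53inp1, Sesn1, Hmmr, E2f1, Cdc6, Fabp4, Smpd3, Dcn, Lum, Ccn1, Ccn2, Chac1, Gsr, Ndrg1, Ndufb5 and Aif1. Leaving out 1 array reversed Hmmr (-0.24 without empty vector replicate 1), Cdc6 (0.31 without empty vector replicate 2 and 0.11 without scramble replicate 2), Dcn (-0.12 without empty vector replicate 2) and Myh11 (-0.42 without shIRF7 replicate 1).

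Against each control alone fewer genes passed. Against scramble, which controls for the presence of a hairpin, Rnf141 fell by 2.01 on the log2 scale (adjusted p = 0.0494) and was the only gene past the limma threshold, with 1197 genes at an unadjusted p under 0.05. Its difference from scramble was -1.88 within replicate 1 and -1.92 within replicate 2. With the replicate number as a block 0 genes passed against scramble in limma (smallest adjusted p = 0.381, 563 at an unadjusted p under 0.05). Against empty vector, which controls for infection, 0 genes passed in limma, the smallest adjusted p was 0.0756, and 1139 genes had an unadjusted p under 0.05. The interferon-stimulated list had medians of -1.21 against scramble and -1.25 against empty vector, and fell with camera in both (adjusted p = 6.72e-26 and 1e-32; adjusted p = 0.235 and 0.155 with an estimated correlation). Its medians within replicates 1 and 2 were -1.52 and -1.23 against scramble, and -1.71 and -1.24 against empty vector. Camera called 10 lists against scramble and 8 against empty vector, and 0 in either with an estimated correlation. The count of genes, not lists, against scramble was 8 without shIRF7 replicate 1 (5 lower and 3 higher). Without scramble replicate 1 or 2 only 1 scramble array was left, and the call of Rnf141 was not kept. The gene count against scramble was 0 without any of shIRF7 replicate 2, shIRF7 replicate 3 and shIRF7 replicate 4. Against empty vector it was 1 without empty vector replicate 1, 3 without empty vector replicate 2 (2 lower and 1 higher) and 1 without shIRF7 replicate 4.

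In scramble against empty vector, the comparison of the controls with each other, 0 genes passed in limma (376 at an unadjusted p under 0.05). Camera called 3 lists, all higher in scramble: mitosis and proliferation (median 1.11, adjusted p = 3.15e-05), S phase (median 0.70, adjusted p = 0.0341) and cholesterol synthesis (median 0.49, adjusted p = 0.0185). With an estimated correlation their adjusted p-values were 0.954, 0.967 and 0.954. The difference lay in replicate 1, where the medians were 2.15, 1.34 and 0.90, against 0.028, 0.050 and -0.052 in replicate 2. Relative to the mean of all controls, the mitosis list mean was -2.61 in empty vector and -0.47 in scramble in replicate 1, and 1.53 and 1.55 in replicate 2. The interferon-stimulated list had a median of -0.20 (adjusted p = 0.0852; -0.26 within replicate 1 and -0.079 within replicate 2) and Irf7 differed by 0.08.

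The mitosis and S phase lists separated the control replicates. In replicate 2 minus replicate 1, averaged over both controls, the mitosis list had a median of 2.97 (4.01 in empty vector and 2.00 in scramble) and the S phase list 2.80 (3.37 and 2.29), against -0.04 over all genes, which normalization between arrays holds near 0. The stress response and cholesterol lists had medians of 1.01 each. The first principal component held 43.8% of the variance. The closest arrays were shIRF7 replicates 2 and 3 (SD of the difference over genes 0.322) and replicate 2 of empty vector and scramble (0.325). The other pairs ranged from 0.495 to 0.942. For shIRF7 replicate 1 the SD was 0.544 to shIRF7 replicate 4, but 0.699 and 0.706 to shIRF7 replicates 2 and 3. To scramble replicate 2, empty vector replicate 2, scramble replicate 1 and empty vector replicate 1 it was 0.559, 0.572, 0.580 and 0.842.

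**Figure D4:**
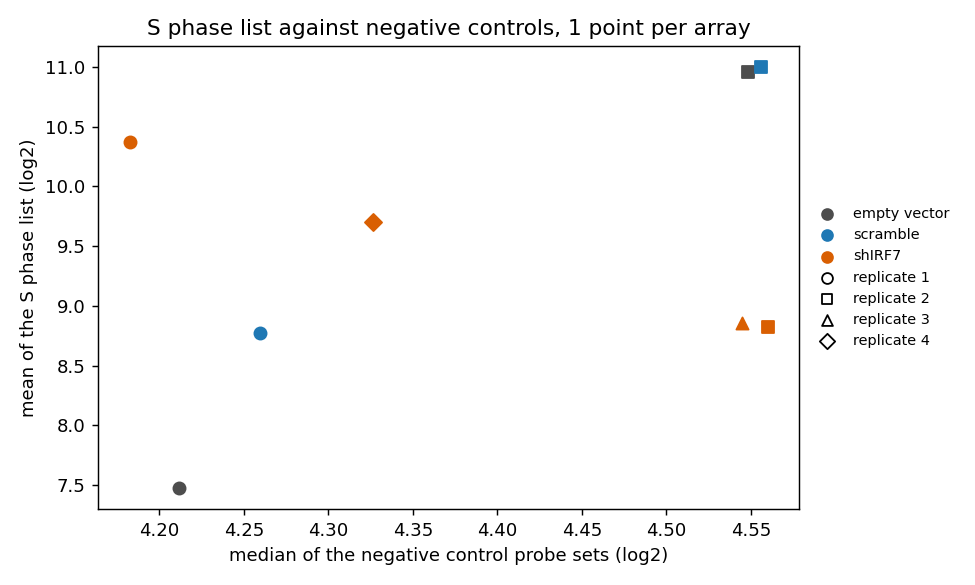
Mean of the S phase list (log2) against the median of the negative control probe sets (log2), with 1 point per array, colour for the group and shape for the replicate number. Empty vector replicate 2, with negative controls of 4.55, had an S phase mean of 10.96, while shIRF7 replicates 2 and 3, with negative controls of 4.56 and 4.54, had means of 8.82 and 8.86.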

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

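Only the counts of splits were planned before their results were seen; the other tests in this part were chosen afterwards, and those on growth state, leukocytes and negative controls were changed after a version of each had been run. Among 89 genes and list means of the 4 shIRF7 arrays, 11 had an array far from the other 3, where chance gives about 4.45, and in 9 of the 11 it was shIRF7 replicate 1.

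The ratio of the gap to the whole range was 0.940 for Dcn (7.62 in replicate 1, then 14.0, 14.1 and 13.7), 0.968 for Lum (4.81, then 6.80, 6.74 and 6.73), 0.945 for Myh11 (7.06, then 3.80, 3.61 and 3.71) and 0.901 for Fabp4 (9.01, then 7.03, 7.09 and 7.23). It was 0.925 for Sesn1 (10.2, then 12.1, 12.2 and 12.1) and 0.920 for Ndufb5 (11.2, then 12.0, 12.0 and 12.0). List means with replicate 1 apart were MHC class I antigen presentation (0.974; 9.69 against 10.4 in the others), interferon signalling and sensing (0.927; 8.74 against 9.18, 9.19 and 9.21) and epithelial markers (0.917; 3.42 against 3.35, 3.35 and 3.34). Replicate 4 stood apart in Cd53 (0.850; 9.72 against 7.45, 7.76 and 7.41) and in the adipocyte list (0.925; 7.04 against 7.25, 7.27 and 7.27).

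The lower interferon-stimulated genes in shIRF7 were weighed against growth state, leukocytes and chance. The S phase means of all 4 shIRF7 arrays lay inside the range of the controls, over which the interferon list mean ranged by 0.45, against a smallest shIRF7 difference of -0.96. Scramble replicate 1, with an S phase mean of 8.77, had an interferon list mean of -0.27, and shIRF7 replicates 2 and 3, with 8.82 and 8.86, had -1.45 and -1.46. This argues against growth state, as S phase genes show it, as the whole cause. Fewer leukocytes in the shIRF7 cultures stay open. Of 19 leukocyte markers 3 lay above the mean negative control median, too few to decide, with a median change of -0.18. Cd53 differed by -0.49 (95% interval -1.88 to 0.90), Cd14 by -0.18 (-0.56 to 0.19) and H2-Ab1 by 0.04 (-0.29 to 0.38). At least as many members past the threshold of the list alone (31) came from 2 of 100 drawn splits into 2, 2 and 4 arrays. These include the real split, and the other, with 33, exchanges the roles of shIRF7 and controls. No drawn split that mixed shIRF7 with control arrays reached this count. Replicates may be technical and not independent, so chance is not excluded. Lower Irf7 remains open as a hypothesis for these genes, and so does an off-target effect of the hairpin, which was not tested.

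Counts of genes do not exclude chance. Of the 100 drawn splits, 8 gave at least as many genes as the real 6, and the highest other gave 926; with both controls as 1 group, 3 of 35 splits gave at least the real 28, and the highest other gave 315. Such splits point to a structure of the samples. The split with 926 set replicate 1 of both controls with shIRF7 replicates 2 and 3, the 4 arrays with the lowest S phase means. As 4 against 4 it gave 176. The split with 315 exchanged shIRF7 replicate 1 and empty vector replicate 1. For lists, 4 of 100 splits gave at least the real 12, the real split included, a share just under 0.05. The 3 others each gave 13, more than the real split, and the median over the 99 other splits was 8. Only some of the possible splits were drawn, so that share is itself uncertain. The count of lists does not stand apart and does not exclude chance.

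Growth genes set control replicates 1 and 2 apart, and no biological explanation was tested, since the design names none. Processing tracked by the negative controls would raise the S phase list in the shIRF7 arrays with the highest negative controls, but their mean lay -1.20 from the other 2 (8.82 and 8.86 against 10.4 and 9.70). Density or passage of the cultures was not tested, nor was array scaling, since the values were already normalized between arrays.

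shIRF7 replicates 2 and 3 may come from a shared culture or RNA. The SD of their difference was 0.322, against 0.325 between replicate 2 of empty vector and of scramble, which carry different vectors. Other pairs of different vectors ranged from 0.554 to 0.942. The pair at 0.325 shares a replicate number and may itself share a source, so it is no sure measure of likeness between unrelated samples. Shared material and chance likeness therefore cannot be told apart.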

How the results depend on the processing

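The S phase covariate and the averaging of shIRF7 replicates 2 and 3 were chosen after seeing the data. Irf7 was lower under all 17 alternatives (-4.58 to -3.31, adjusted p 0.0248 to 0.316) and passed in 3: both controls as 1 group (-3.79, adjusted p = 0.0299), the covariate (-3.80, 0.0248) and without shIRF7 replicate 1; leaving out arrays gave -4.10 to -3.31. Probe sets near background limit what can be seen, since 31.6% to 36.8% of named probe sets exceeded the 95th percentile of the negative controls.

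The count of 6 genes was 3 with trend and robust fitting, 1 over all probe sets (0 of them unnamed), 28 with both controls as 1 group (3 higher, 25 lower, 5 shared with the 6), 0 with the replicate block, 3 with array weights, 0 at an adjusted p under 0.01, 131 with the covariate (44 higher, 87 lower, all 6 included), 0 with replicates 2 and 3 averaged, and 0 to 28 leaving out arrays. The single gene against scramble became 0 with the dim filter, trend and robust fitting, all probe sets, the replicate block, an adjusted p under 0.01 and averaging, 14 with the covariate, and 0 to 8 leaving out arrays. Against empty vector the 0 became 8 with the covariate and 0 to 3 leaving out arrays; scramble against empty vector stayed at 0 in all. Where arrays or genes tested differed the construction alone can move a count; for the rest the cause was not tested. A control left alone was assumed to vary like the other groups.

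The 12 lists became 0 with an estimated correlation and 4 with fry, and were 8 to 11 leaving out arrays. With array weights 8 passed, and interferon signalling (-0.048), chemokines (-0.045), mitosis (0.38) and collagens (-0.27) lost the call. Of 11 each, the dim filter lost mitosis, camera on ranks interferon signalling, and the covariate and averaging contractile genes (-0.38 and -0.14). The interferon-stimulated, GTPase and oxidative phosphorylation lists passed in 19 of 20 alternatives each (medians of -1.53 to -0.94 for the first and 0.19 to 0.27 for the last). The exception was the estimated correlation. Most of the 20 repeat camera with a preset correlation on the same or nearly the same arrays. That test called a median of 8 lists in other splits, so passing in 19 is not separate support.

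Deviations of same-numbered empty vector and scramble arrays from their group means correlated at 0.757; with 2 arrays per group these mirror each other, so this is 1 observation and own-number matches of the controls add nothing. Same-numbered shIRF7 and control arrays correlated negatively (-0.310, -0.225, -0.209 and -0.161), and shIRF7 replicates 1 and 2 did not match best with their own number, so a pairing was not shown. With the replicate block Irf7 differed by -4.58, and 10 lists passed; the contractile (-0.16) and glycolysis (-0.096) lists did not.

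Directions reversed, none of these past the threshold, for senescence (0.045 dim filter, 0.071 block), adipocyte genes (-0.0032 dim filter, -0.0083 covariate, -0.033 averaged), S phase genes (0.098 block, 0.036 covariate, 0.096 averaged), chondrogenic genes (-0.0034 block, -0.0035 covariate, -0.035 averaged), macrophage markers (0.016 block), endothelial markers (-0.022 block), Dcn (-0.30 block), NF-kappa-B (0.023 weights), p53 targets (-0.061 weights) and Myh11 (-0.0078 weights). The cause was not tested. Leaving out arrays reversed interferon signalling (-0.21 to 0.019), NF-kappa-B (-0.13 to 0.083), p53 (-0.055 to 0.19), mitosis (-0.49 to 1.60), S phase (-1.04 to 0.76), adipocyte (-0.057 to 0.17), chondrogenic (-0.13 to 0.11), stromal (-0.13 to 0.066), stress response (-0.62 to 0.011), Nrf2 (-0.12 to 0.092), macrophage (-0.11 to 0.0010), lymphocyte (-0.11 to 0.027), endothelial (-0.015 to 0.14) and pericyte (-0.24 to 0.062) lists, and Hmmr (-0.24 to 2.50), Cdc6 (-1.52 to 0.31), Dcn (-0.12 to 2.80) and Myh11 (-0.42 to 0.73). Of these, mitosis without empty vector replicate 1 and S phase without empty vector replicate 2 passed the threshold in the reversed direction.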

Other observations

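Members of the interferon lists did not all differ alike, and the genes in this paragraph were chosen after their values were seen. Trim30a, a restriction factor, differed by -4.62 (understated, since shIRF7 replicates 1 and 2, at 3.43 and 4.30, lay below the mean negative control median of 4.40) and Usp18, a brake on interferon receptor signalling, by -3.66, while Ifitm3, also interferon-stimulated, differed by -0.07. In the signalling list Jak1 differed by -1.35 and Irf9 by -1.40, while Ifnar1, Irf3 and Mavs differed by 0.13, 0.14 and 0.37. Grem1, a secreted BMP antagonist, differed by 2.51 (adjusted p = 0.0692).

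A hypothesis tested after the data were seen was that the scrambled hairpin itself raises interferon genes. The interferon-stimulated list median in scramble minus empty vector was -0.20 (camera adjusted p = 0.0852; adjusted p = 0.954 with an estimated correlation). The list means of scramble (-0.27 and 0.05) and empty vector (0.03 and 0.19) overlapped, so the hypothesis stays open.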
